A study of Homo sapiens with 64 samples.

How the data were processed

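RNA was measured by BRB-seq, a multiplexed bulk method that reads the 3' end of polyadenylated transcripts. Per the labels' protocols, total RNA was extracted with a column kit, its integrity was measured on a fragment analyzer, and libraries were prepared and sequenced by a service provider. The deposited values are whole-number counts per gene, not normalized, in 2 tables of 60664 genes, 1 per compound, each with its 32 libraries. Per the submitters' processing notes, FastQC 0.11.9, STAR and SAMtools 1.12 were used with the human build hg38 (GRCh38). The version of STAR, the counting tool, the annotation release, the strand setting and whether unique molecular identifiers were collapsed are not given in the sources used here. The values are therefore treated as read counts, and intervals and floors cover counting error only. Reads of near-identical copies (histones, metallothioneins, mitochondrial pseudogenes) and of overlapping genes could be split or dropped by the counting, so such genes are uncertain. Reads come from the 3' end only, so no statement about isoforms is made. Gene symbols were matched by Ensembl identifier for 60463 genes, and positions were taken from GENCODE v29 (GRCh38) for 58396 genes, a copy that may differ from the annotation used for counting.

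Libraries were grouped by the compound, dose and time in their titles and treatment labels, 16 groups of 4. Columns were matched to libraries by name, and no column was without a library. No pair of libraries of a group was a duplicate: a chi-square over genes per degree of freedom lay between 2.67 and 11.8 over 96 pairs. The first principal component of log2 CPM held 7.3% of the variance in the PGBE table and 40.8% in the 2BPA table. The tables differed in background reads, judged by 404 olfactory receptor genes, which are rarely expressed outside the nose. These genes took between 10 and 231 CPM in 2BPA and between 1.5 and 10.7 CPM in PGBE libraries. Levels were therefore compared within a table only, and compounds only through the difference of their effects.

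Testing used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures used Python 3.11.15 with matplotlib 3.10.9. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 13840 genes for PGBE, 15532 for 2BPA and 15913 for both. Counts were scaled by TMM and fitted by edgeR's quasi-likelihood model with robust dispersion, 1 mean per group and no covariates, over all 32 libraries of a compound, and over all 64 for the differences between compounds. The common biological coefficient of variation was 0.111 for PGBE, 0.155 for 2BPA and 0.134 for both. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and every adjusted p of a gene is from this test. The median log2 fold change of all genes lay within 0.1 of 0 in every comparison. Intervals of differences between compounds use a t quantile on 48 residual degrees of freedom. They are per gene and not adjusted over genes, so an interval can exclude 0 where the adjusted p does not pass. For a gene with 0 counts in a group, a bound is given from a floor of 3 counts per group, and with 1 to 3 counts the ratio with its exact 95% interval. These bounds and ratios use raw group totals without TMM scaling, unlike the fitted fold changes.

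The comparisons were each dose with untreated libraries of the same compound and time, the 1 week minus the 24 h effect at 20 mM, untreated libraries between times, and the PGBE minus the 2BPA effect at each dose and time. Tested on 33 gene lists of cell types and pathways with camera, a list was called at an adjusted p under 0.05 over the lists with at least 3 measured members, with the correlation between genes estimated, and 0.01 preset as an alternative. Every list call stated is with the estimated correlation, and list counts are over all genes tested and adjusted over the list alone. Of the 33 lists, APOE, ALDOC, SLC7A11, ME1 and AQP1 each stand on more than 1. Library measures (total counts, genes detected and shares of counts) were compared by exact two-sided permutation tests over 70 assignments, with a smallest p of 0.029.

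The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. By that rule, genes with a symbol were named in 4 ways, leaving out XIST and Y-linked genes. Each main comparison (20 mM with untreated) gave the 5 largest rises and falls among called genes with at least 10 CPM in the higher group and no overlap of the libraries, and the members of a described list with the smallest adjusted p. Differences between compounds, times and untreated libraries gave the 4 largest in each direction, and other doses the 3 largest. Of genes named by the parts on differences and lower doses, those whose call ended on leaving out 1 library are not described unless the count was 5 or fewer. Results of 2 genes that the rule takes are not reported here. Other genes (such as TFRC at each dose and time, JUN, HSPA4L, SLC7A11, MALAT1 and the genes followed across doses of 2BPA) were chosen after their values were seen. So were the direct comparisons of 2BPA doses and 3 settings. These were background reads on olfactory receptor genes as covariate, thinning every library to the smallest total (2755316, 1559252 and 1559252 counts), and leaving out 4 libraries that stood apart in depth or on the principal components (untreated 24 h D and 20 mM 1 week A for PGBE, 10 mM D and 20 mM A of 1 week for 2BPA). Further comparisons (10 with 5 mM 2BPA after 1 week, and time differences at lower doses) were computed, looked at and not kept. The alternatives set beforehand were DESeq2-style size factors, no filter, the letter as block, DESeq2, only the compared libraries, and leaving out each library in turn.

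The scripts were tested on simulated data drawn from the means and library sizes of the real groups, with 200 genes changed. At 1.5-fold, 2-fold and 4-fold changes, edgeR recovered 44.8%, 71.6% and 95.5% of changed genes for 20 mM PGBE at 24 h (8 of 13622 unchanged genes called). The shares were 35.8%, 58.2% and 75.8% for 2BPA at 24 h (4 of 15314), 38.8%, 73.1% and 80.3% for 2BPA after 1 week (4 of 15314), and 19.4%, 59.7% and 72.7% for the compound difference at 24 h (6 of 15695). No gene was called in the wrong direction. A gene list shifted by 1.5-fold was called in each of the 4 simulations and 0 of 30 other lists were. Simulated genes were drawn independently, so these numbers do not give error rates under the correlation and structure of the real libraries.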

Results

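Transcripts were counted in BrainSpheres, free-floating spheroids of neurons, astrocytes and oligodendrocyte-lineage cells grown from human induced pluripotent stem cells. The cells came from the CCD-1079Sk skin fibroblast line (CRL-2097). Spheroids aged 7 weeks were exposed to propylene glycol butyl ether (PGBE), a glycol ether solvent, or to 2-butoxypropanoic acid (2BPA), named in the labels as its metabolite. PGBE is a butyl ether that carries an alcohol group, and 2BPA carries a carboxylic acid. The doses were 0, 5, 10 and 20 mM, given as 1 exposure with collection after 24 h or as 3 exposures over 1 week. Each of the 16 groups held 4 libraries, marked A to D, for a total of 64. Each compound had its own untreated libraries at both times. The treatment labels write the doses in micromolar and the exposure protocol and series design in millimolar, which is used here. The title of the series names the neurotoxicity of PGBE, so the comparisons ask which transcripts moved with dose, with time and number of exposures, and with the parent compound against its metabolite. Total counts per library ran from 2755316 to 5150847 for PGBE (median 4058466.5) and from 1559252 to 6355971 for 2BPA (median 4611493.5). Values are in CPM, counts scaled to a common library total, as mean ± SD with n = 4 per group. Log2 fold changes carry their standard error. The labels do not say that A to D were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

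**Figure D1:**
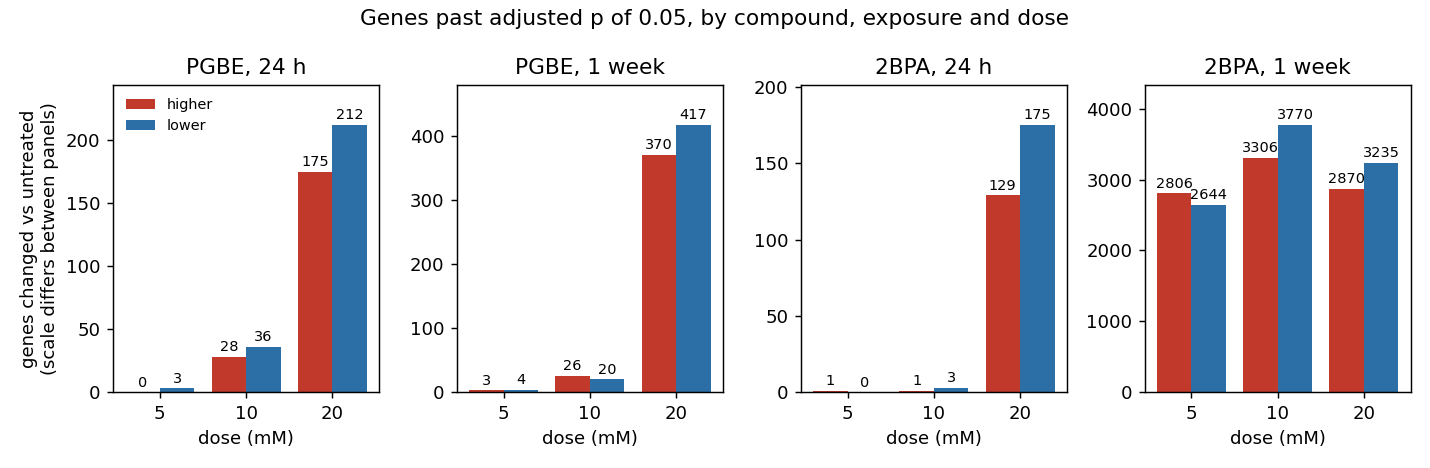
Number of genes higher (red) and lower (blue) than in the untreated libraries of the same compound and time, at an adjusted p under 0.05, by dose in mM. The vertical scale differs between panels, from at most 212 genes for PGBE at 24 h to 3770 for 2BPA after 1 week.

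After 1 exposure to 20 mM PGBE, genes of the amino acid response, the program driven by the transcription factor ATF4, were higher than in untreated spheroids. MTHFD2, a mitochondrial enzyme of folate metabolism (ENSG00000065911, chromosome 2, 74198562 to 74217565, plus strand, GRCh38), rose 1.92-fold, from 77 ± 3.57 to 148 ± 11.7 CPM (log2 0.94 ± 0.0882, adjusted p = 5.4e-18). SLC3A2, the heavy chain of several amino acid transporters, rose 1.53-fold. PHGDH, the first enzyme of serine synthesis, rose 1.43-fold and SESN2, a stress-induced regulator of mTORC1, 1.5-fold. Of the 21 measured members of this list 9 rose, or 13 with 1 lower when adjusted over the list alone (camera adjusted p = 0.00017). Neuronal cytoskeleton and identity genes moved down: 5 of 14 fell, and 5 when adjusted over the list alone (camera adjusted p = 0.00601). STMN2, a microtubule regulator of growing axons (ENSG00000104435, chromosome 8, 79610814 to 79666175, plus strand), was 1.33-fold lower at 1320 ± 50.4 against 1760 ± 59.2 CPM (log2 -0.41 ± 0.0403, adjusted p = 1.36e-16). The neurofilament-like INA was 1.21-fold lower (adjusted p = 4.12e-05) and the growth cone protein GAP43 1.19-fold lower (adjusted p = 0.000128). Targets of p53 rose in 4 of 21 cases, or 7 over the list alone (camera adjusted p = 0.00865), among them CCNG1 at 1.34-fold and the apoptosis effector BAX at 1.49-fold. Chaperones of the endoplasmic reticulum rose in 3 of 18 cases, or 5 over the list alone (camera adjusted p = 0.0123), led by the unfolded protein response factor XBP1 at 1.48-fold and the lectin chaperone CANX at 1.21-fold. Presynaptic genes went both ways, with 2 higher and 4 lower of 18 (3 and 5 over the list alone, camera adjusted p = 0.516). PCLO, a scaffold of the presynaptic active zone (ENSG00000186472, chromosome 7, 82754013 to 83162930, minus strand), rose 2.12-fold, from 85.5 ± 3.47 to 181 ± 21.5 CPM, while the calcium sensor SYT1 was 1.19-fold lower (adjusted p = 0.000579).

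Among the genes with the largest changes at 20 mM PGBE after 24 h, SLC16A6, a transporter of the monocarboxylate family, rose from 5.1 ± 2.33 to 18.3 ± 1.71 CPM (log2 1.77 ± 0.281, adjusted p = 8.45e-07). The cation channel TRPM4 rose 2.33-fold (adjusted p = 0.000764). UQCC5, an assembly factor of respiratory complex III, rose 2.21-fold (adjusted p = 0.00325). JUN, an immediate early transcription factor, rose 1.61-fold (adjusted p = 8.55e-11). So did the chaperone HSPA4L 1.78-fold (adjusted p = 1.46e-06) and SLC7A11, the cystine importer, 1.99-fold (adjusted p = 0.00525). The largest fall was that of the histone gene H4C3, 4.44-fold (adjusted p = 1.24e-29). The anchoring collagen COL7A1 was 3.19-fold lower (adjusted p = 4.16e-06) and MIR124-1HG, the host transcript of a neuronal microRNA, 2.33-fold lower (adjusted p = 1.63e-05). H4C3 has near-identical copies, so its reads may be shared. Its untreated level was itself higher at 24 h (74.5 ± 10.9 CPM) than after 1 week (21.4), as was that of MIR124-1HG (21.1 ± 4.96 against 10.5). The latter difference was not called without untreated 24 h B (adjusted p = 0.058). In all, 387 of 13840 genes changed (175 higher, 212 lower), and 21 of them by at least 2-fold. The calls of CEBPB (higher, adjusted p = 0.0294), FAH (lower, adjusted p = 0.00298) and ZNRD2 (lower, adjusted p = 0.0123) ended on leaving out 1 library. CEBPB lost its call without untreated A (0.105) or B (0.136) or treated A (0.0639), B (0.0561) or C (0.0996). FAH lost it without untreated D (0.0601), and ZNRD2 without untreated C (0.0513) or treated A (0.111) or B (0.062). The list calls for neuronal identity (adjusted p = 0.102), the amino acid response (0.0836), endoplasmic reticulum chaperones (0.102) and p53 targets (0.15) ended when only the 8 compared libraries were fitted. That for the chaperones also ended without treated library A (0.0513).

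At 10 mM PGBE after 24 h, JUN rose from 83.2 to 122 CPM (log2 0.55, adjusted p = 3.13e-06). SLC43A2, an amino acid transporter, rose from 88.3 to 127 CPM (log2 0.53, adjusted p = 4.52e-06), and H4C3 fell (log2 -1.74, adjusted p = 7.08e-22). These were among 64 genes changed (28 higher, 36 lower), or 115 (59 higher, 56 lower) by DESeq2, 32 without a filter on low counts and 40 without the libraries that stood apart. At 5 mM 3 genes fell, among them those of the axonal growth proteins STMN2 (log2 -0.19, adjusted p = 0.0185) and BASP1 (log2 -0.23, adjusted p = 0.01). No gene rose, with 797 genes at an unadjusted p under 0.05. With only the 8 compared libraries fitted the 5 mM count was 5, and on thinning it was 0. Both counts depended on single libraries. That at 10 mM fell to 28 without untreated A, 35 without B, 26 without C, 38 without D, 26 without treated A, 42 without C and 20 without D. That at 5 mM fell to 0 without untreated A or B or treated B and to 1 without treated D. The call of STMN2 ended without untreated A (0.0806), B (0.341) or D (0.129) or treated B (0.392), C (0.209) or D (0.249). That of BASP1 ended without untreated A (0.0817), B (0.163) or C (0.0568) or treated B (0.392) or D (0.0734).

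After 3 exposures to 20 mM PGBE over 1 week, cell cycle genes were lower together. TOP2A, the topoisomerase that untangles replicated DNA (ENSG00000131747, chromosome 17, 40388516 to 40417950, minus strand), was 2.57-fold lower, at 39.8 ± 9.23 against 102 ± 12.4 CPM (log2 -1.36 ± 0.114, adjusted p = 2.26e-19). The proliferation marker MKI67 was 2.49-fold lower (17.9 ± 4.75 against 45 ± 3.75 CPM) and the mitotic survivin gene BIRC5 2.29-fold lower. Of 22 measured proliferation genes 20 fell, or 21 over the list alone (camera adjusted p = 4.91e-08, median log2 -1.04). Neural progenitor markers fell in 4 of 11 cases, or 8 over the list alone (camera adjusted p = 0.00237). FABP7, a fatty acid binding protein of radial glia, was 1.45-fold lower (529 ± 30.6 against 765 ± 41 CPM), and the growth factor receptor FGFR3 1.43-fold lower. Astrocyte markers fell in 2 of 11 cases, or 2 over the list alone (camera adjusted p = 0.0104), and S100B, a calcium-binding protein of astrocytes, fell from 26.8 ± 1.75 to 8.65 ± 3.34 CPM (log2 -1.62 ± 0.223, adjusted p = 3.02e-09).

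Genes of sterol synthesis and uptake were also lower after 1 week of PGBE at 20 mM. HMGCS1, the enzyme that makes HMG-CoA for sterol synthesis (ENSG00000112972, chromosome 5, 43289395 to 43313512, minus strand), was 1.41-fold lower at 364 ± 30.1 against 513 ± 37.5 CPM (log2 -0.50 ± 0.0546, adjusted p = 3.54e-13). FDPS and IDI1, later enzymes of the same path, were each 1.34-fold lower. Of 23 measured members 8 fell, or 9 over the list alone (camera adjusted p = 0.00237). Transcripts of the mitochondrial genome were higher: 8 of 13 rose, or 9 over the list alone (camera adjusted p = 0.00368). MT-ND2, a complex I subunit (ENSG00000198763, mitochondrial genome, 4470 to 5511), rose 1.3-fold to 2700 ± 88.2 CPM. MT-CO1, a cytochrome oxidase subunit, rose 1.55-fold to 4310 ± 36.4 CPM. The amino acid response stayed higher, with 6 of 21 genes up, or 7 over the list alone (camera adjusted p = 0.00237). MTHFD2 rose 1.84-fold (161 ± 15.1 against 88.2 ± 6.75 CPM), SLC3A2 1.46-fold and SHMT2, a mitochondrial serine enzyme, 1.33-fold. Postsynaptic genes (1 of 16 higher, 4 over the list alone, camera adjusted p = 0.0104), presynaptic genes (3 of 18 higher, 3 over the list alone, camera adjusted p = 0.0478) and autophagy genes (1 of 20 higher, 1 over the list alone, camera adjusted p = 0.0478) moved up as lists. The vesicle protein VAMP2 rose 1.39-fold and PCLO by log2 0.91 (adjusted p = 2.58e-07). The nuclear RNA MALAT1 rose 2.03-fold, from 1430 ± 237 to 2910 ± 642 CPM. Ribosomal protein genes, with 7 of 25 higher (11 over the list alone) and RPS3 at 1.25-fold, passed camera with a preset correlation only (adjusted p = 0.26 with an estimated correlation).

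After 1 week of 20 mM PGBE the spindle checkpoint kinase BUB1 fell from 13 ± 1.01 to 2.42 ± 1.46 CPM (log2 -2.40 ± 0.32). The kinase MELK was 3.83-fold, the centromere chaperone HJURP 3.68-fold and ACBD7 3.23-fold lower (adjusted p = 0.000131). TRPM4 rose 2.05-fold (adjusted p = 0.00904). In all 787 genes changed (370 higher, 417 lower), 110 by at least 2-fold. The treated libraries were shallower (mean 3146000 against 4132000 counts) and held larger shares of mitochondrial transcripts (8.19% against 7.04%) and ribosomal protein transcripts (16.1% against 15.2%). The 20 most abundant genes also took a larger share (14.95% against 13.73%). Each of these measures had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows, and 0.158 after adjustment over 72 tests. The calls of GRIK3 (adjusted p = 0.0177), MDGA2 (0.0133), PDIA2 (0.00586) and HSF4 (0.0106), all higher, ended on leaving out 1 library. That of GRIK3 ended without untreated D (0.105) or treated A (0.0674) or C (0.0852), MDGA2 without untreated A (0.104) or treated D (0.0541). PDIA2 lost its call without untreated D (0.0525), and HSF4 without untreated A (0.0623) or treated B (0.0522) or C (0.0648). The presynaptic list call ended without untreated B (0.0616), C (0.0581) or D (0.0552) or treated B (0.0889) or C (0.086). That of autophagy ended without untreated A (0.0512), C (0.0581) or D (0.101) or treated B (0.0856) or C (0.0979). With only the 8 compared libraries fitted, the presynaptic (adjusted p = 0.125) and autophagy (0.149) calls and those of postsynaptic, astrocyte, progenitor and amino acid response genes (0.0573 each) ended. The presynaptic and autophagy calls also ended without a filter on low counts (0.0902 and 0.0539) and with the background covariate (0.054 and 0.0564), and the presynaptic call on thinning (0.0619). Those of proliferation, sterol and mitochondrial genome genes held.

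Sterol, cell cycle and mitochondrial genome genes also moved at lower doses of PGBE after 1 week, and the doses were not tested against each other. HMGCS1 was lower at 5 mM already (387 ± 28.7 against 513 ± 37.5 CPM, log2 -0.40, adjusted p = 4.04e-08), as was the sterol list, with 2 genes lower, or 10 over the list alone (camera adjusted p = 0.00206, median log2 -0.21). At 10 mM the sterol list was lower (4 genes, 7 over the list alone, camera adjusted p = 0.00144). Proliferation genes were lower (1 gene, 12 over the list alone, camera adjusted p = 0.000638, median log2 -0.36), and mitochondrial genome transcripts were higher (7 of 13, 8 over the list alone, camera adjusted p = 0.00135, median log2 0.27). The mitochondrial share of counts at 10 mM was 8.2% against 7.04% (exact two-sided permutation p = 0.0286, adjusted p = 0.158). At 5 mM 7 genes changed, among them also H4C3 (log2 0.87) and the ribosomal protein gene RPS3 (log2 0.23), both higher. At 10 mM 46 genes changed (26 higher, 20 lower). By DESeq2 the counts at 5 and 10 mM were 25 and 113, and with only the 8 compared libraries fitted they were 12 and 80. The 5 mM count was 3 without treated B and 4 without treated C. The 10 mM count was 30 without untreated A, 29 without untreated D, 27 without treated B and 23 without treated D.

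After 1 exposure to 2BPA, the transcript with the clearest change was TFRC, the transferrin receptor through which cells take up iron (ENSG00000072274, chromosome 3, 196027183 to 196082189, minus strand). It stood at 31.3 ± 2.8 CPM in untreated libraries and at 76.5 ± 5.6, 105 ± 0.916 and 102 ± 10.3 CPM at 5, 10 and 20 mM, rises of 2.44-fold, 3.34-fold and 3.26-fold (adjusted p = 4.81e-10, 5e-15 and 1.06e-14). At 5 mM it was the 1 gene called, with 457 at an unadjusted p under 0.05. At 10 mM 4 genes were called, TFRC with ARRDC4 and the mitotic genes UBE2C and CDC20. With only the 8 compared libraries fitted the number was 293 (81 higher, 212 lower), and by DESeq2 it was 51. Only TFRC was called without treated B, C or D or untreated B or C (1 gene each), and 2 genes without treated A or untreated D. The call of CDC20 ended without any 1 of the 8 libraries (adjusted p = 0.0816 to 0.296), and that of ARRDC4 without any of them but untreated A (0.116 to 0.2). UBE2C lost its call without untreated B (0.0859) or C (0.11) or treated B (0.178), C (0.0671) or D (0.0823).

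**Figure D2:**
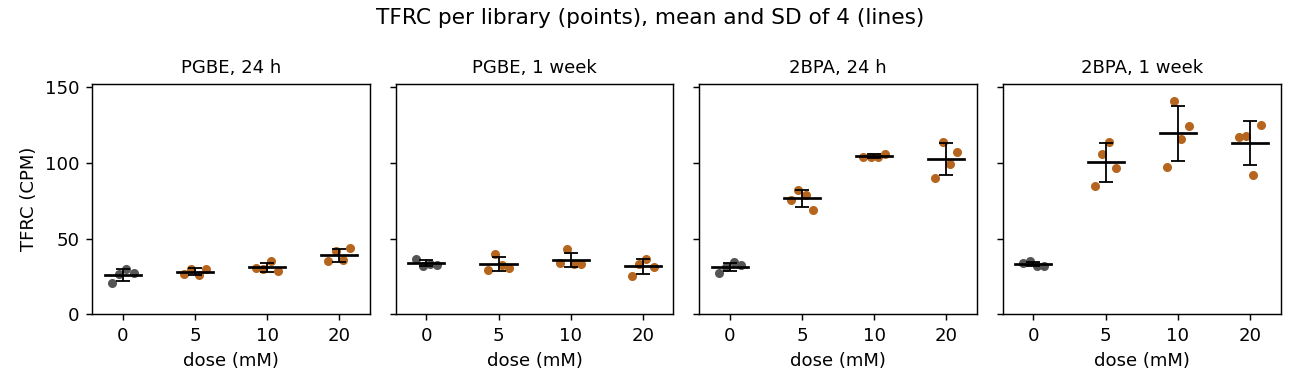
TFRC in CPM in each library (points), by dose in mM, for both compounds and exposure times, with the mean and SD of 4 libraries (lines). With 2BPA at 24 h the untreated mean is 31.3 and the means at 5, 10 and 20 mM are 76.5, 105 and 102.

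At 20 mM 2BPA after 24 h, genes of DNA replication were lower and the amino acid response was higher. MCM4 and MCM5, subunits of the replicative helicase, were 1.77-fold and 2.11-fold lower (MCM4 at 56.9 ± 2.74 against 101 ± 12.2 CPM, log2 -0.82 ± 0.134, adjusted p = 0.000179). GINS2, which works with that helicase, was 2.41-fold lower (16.7 ± 2.16 against 40.3 ± 6.7 CPM, adjusted p = 3.97e-05). Proliferation genes fell in 10 of 22 cases, or 17 over the list alone (camera adjusted p = 5.59e-08, median log2 -0.66). At 10 mM the list was lower with no single gene of it called by edgeR, or 7 over the list alone (camera adjusted p = 1.32e-06, median log2 -0.41). Of the amino acid response 6 of 22 genes rose, or 9 with 1 lower over the list alone (camera adjusted p = 0.00796). SLC7A11, the cystine importer (ENSG00000151012, chromosome 4, 138164097 to 138242349, minus strand), rose 2.97-fold from 8.44 ± 3.25 to 24.9 ± 1.92 CPM (adjusted p = 2.21e-05). CEBPB, a partner of ATF4, rose 2.15-fold and MTHFD2 1.5-fold. The radial glial genes FABP7 (1.65-fold) and VIM (1.33-fold) were lower. PALM3 rose 3.32-fold (adjusted p = 6.95e-05) and SHFL, an interferon-induced antiviral gene, 2.3-fold (adjusted p = 6.4e-05). Subunits of the respiratory chain encoded in the nucleus moved down slightly, 3 of 28 called and 13 over the list alone (camera adjusted p = 0.0325). Ribosomal protein genes fell in 4 of 25 cases, or 14 over the list alone (adjusted p = 0.243 with an estimated correlation). Their share was 13.3% against 14.5% of counts (exact two-sided permutation p = 0.0286, adjusted p = 0.158).

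In all, 304 of 15532 genes changed at 20 mM 2BPA after 24 h (129 higher, 175 lower), 48 by at least 2-fold. The count depended on the libraries and the method: 1494 genes were called from the 8 compared libraries alone, 789 (295 higher, 494 lower) by DESeq2, and 141 with every library thinned to the smallest total, a setting chosen after seeing the data. It was 117 without untreated B, 101 without C, 172 without D, 177 without treated A, 165 without B, 110 without C and 140 without D. The call of the respiratory chain list ended without untreated B (0.0541) or treated B (0.0874) and on thinning (0.109). That of the amino acid response ended on thinning (0.0631). The call of NAV2 (higher, adjusted p = 0.0384) ended without untreated A 0.107, C 0.181 or D 0.09 or treated A 0.0625, B 0.0989, C 0.0723 or D 0.121. So did those of H4C3 (lower, adjusted p = 0.0146) without untreated C (0.0573) or treated D (0.0696) and of MIR4453HG (lower, adjusted p = 0.012) without untreated C (0.0573) or treated C (0.0763). The call of DHRS2 (lower, adjusted p = 0.00523) ended on thinning (0.0823), as did that of MIR4453HG (0.308).

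Repeated exposure to 20 mM 2BPA over 1 week moved a large part of the transcriptome. The treated libraries were shallower, at a mean of 2975000 against 4757000 counts (exact two-sided permutation p = 0.0857, adjusted p = 0.28). Cell division genes were far lower: TOP2A stood at 2.62 ± 1.05 against 63.5 ± 10 CPM, 22.8-fold lower (log2 -4.51 ± 0.227, adjusted p = 4.49e-21). BIRC5 was 31.6-fold and MKI67 41.5-fold lower, the latter log2 -5.38, or -6.12 without treated A. HJURP (chromosome 2, 233833416 to 233854566) had 0 of 11901871 counts in the treated group against 306 of 19027175 counts in untreated libraries. It was at least 63.8-fold lower at a floor of 3 counts per group. Of 22 proliferation genes 21 fell, or 22 over the list alone (camera adjusted p = 3.97e-08, median log2 -2.78). The amino acid response was high, with 18 of 22 genes up and the serine enzyme PSPH down, in the same numbers over the list alone (camera adjusted p = 2.39e-06). DDIT3, the stress-induced factor also called CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737, minus strand), rose 13.7-fold from 21.1 ± 1.79 to 294 ± 45.4 CPM (log2 3.78 ± 0.166, adjusted p = 2.17e-22). The pseudokinase TRIB3 rose 12.9-fold and CEBPB 12.2-fold. GDF15, a secreted stress cytokine (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand), rose 83.5-fold from 12.1 ± 0.582 to 1020 ± 540 CPM (adjusted p = 2.01e-12).

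Stress lists of other kinds were higher too after 1 week of 20 mM 2BPA. Targets of NRF2, the regulator of oxidative stress defence, rose in 15 of 19 cases with AKR1C1 lower, the same over the list alone (camera adjusted p = 2.46e-05). Among them were the quinone reductase NQO1 at 15-fold (97.3 ± 18.8 against 6.49 ± 1.47 CPM) and the ferritin chains FTL at 7.66-fold and FTH1 at 5.25-fold. Targets of p53 rose in 14 of 20 cases with TP53INP1 and TP53I3 lower (camera adjusted p = 0.000828), with the death receptor TNFRSF10B at 3.85-fold, the apoptosis inducer BBC3 at 3.87-fold and the cell cycle inhibitor CDKN1A at 3.36-fold. Autophagy and lysosome genes rose in 14 of 20 cases (camera adjusted p = 0.00618), with the cargo receptor SQSTM1 at 5.43-fold (1310 ± 202 against 240 ± 15 CPM) and MAP1LC3B at 3.01-fold. Endoplasmic reticulum chaperones rose in 16 of 18 cases with PDIA3 lower (camera adjusted p = 0.0388), with DNAJC3 at 4.89-fold and XBP1 at 4.34-fold. Counts over these 3 lists alone were the same. Transcripts of the mitochondrial genome went the other way: 9 of 13 fell, or 10 over the list alone (camera adjusted p = 0.00144, median log2 -1.78). MT-ND2 was 5.15-fold lower at 513 ± 95 against 2650 ± 158 CPM (log2 -2.36 ± 0.114, adjusted p = 5.92e-21) and MT-CYB, the cytochrome b gene, 4.25-fold lower. The 28 nuclear respiratory chain genes went both ways, with 6 higher and 6 lower, the same over the list alone (camera adjusted p = 0.917). The mitochondrial share of counts was 3.03% against 5.37% (exact two-sided permutation p = 0.0286, adjusted p = 0.158). The call of AKR1C1 ended without treated C (0.0612) or D (0.0745) and that of TP53INP1 without untreated C (0.0608) or treated D (0.114). PDIA3 lost its call without untreated A (0.0537), B (0.0696) or D (0.156) or treated B (0.132) or D (0.109), with the background reads as covariate (0.0672) and on thinning (0.122).

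Neuronal genes were mostly lower after 1 week of 20 mM 2BPA. Of 14 neuronal cytoskeleton and identity genes 9 fell and 2 rose, the same over the list alone (camera adjusted p = 0.0388). This list call ended under some settings, given below. GAP43 was 2.28-fold lower, the RNA-binding protein ELAVL4 2.54-fold lower and STMN2 2.02-fold lower (694 ± 72.6 against 1410 ± 73.7 CPM), while the neurofilament NEFH (1.61-fold) and the ubiquitin hydrolase UCHL1 (1.41-fold) were higher. The call of NEFH ended without untreated D (0.0873) or treated A (0.0887) or B (0.095), without a filter (0.0529) and on thinning (0.0566). Postsynaptic genes fell in 9 of 17 cases, the same over the list alone (adjusted p = 0.0626 with an estimated correlation). Among them the glutamate receptor GRIA1 was 2.38-fold and the adhesion protein NLGN3 2.62-fold lower. The vesicular glutamate transporters went apart, SLC17A6 4.18-fold lower (11.1 ± 4.14 against 49.3 ± 4.22 CPM) and SLC17A7 3.72-fold higher (25.6 ± 5.05 against 6.88 ± 0.549 CPM). OLIG1, a factor of the oligodendrocyte lineage, was 9.27-fold lower (6.2 ± 4.64 against 66.6 ± 2.6 CPM; log2 -3.21, or -3.99 without treated B), within a list of which 3 of 7 fell and 1 rose, the same over the list alone (camera adjusted p = 0.205). FABP7 was 3.61-fold lower and the lipid carrier APOE 4.41-fold higher, within an astrocyte list of which 3 of 13 rose and 4 fell, or 5 over the list alone (camera adjusted p = 0.982). Of the 2 microglial genes measured, TYROBP had 30 counts in treated against 3 in untreated libraries, 2 of them in untreated D, a ratio of 16 (95% exact interval 4.97 to 81.9).

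At this dose and time the small heat shock protein gene CRYAB rose from 5.26 ± 0.667 to 316 ± 240 CPM (adjusted p = 7.34e-08). Large rises were also those of the netrin receptor UNC5B (0.809 ± 0.606 to 33.7 ± 5.45 CPM, adjusted p = 9.26e-11) and of the adhesion receptor ICAM1 (1.85 ± 1.68 to 52.4 ± 10.3 CPM, adjusted p = 5.31e-15). HSPB8, another small heat shock protein gene, had 129 counts against 3, the latter all in untreated A, a ratio of 68.7 (95% exact interval 23 to 338). Its fitted log2 fold change was 5.79, or 8.43 without untreated A. Among the falls, TK1, which makes thymidine nucleotides, had 1 count, in treated B, against 341. The ratio of untreated to treated on raw group totals was 213 (95% exact interval 38 to 8450), and the fitted log2 fold change was -7.30. The cell cycle genes MYBL2 and PBK were 75.9-fold and 47.2-fold lower (0.298 ± 0.217 against 26.9 ± 4.86 CPM for MYBL2). PIMREG stood at 0.28 ± 0.397 against 27.5 ± 2.24 CPM, log2 -6.01, or -7.43 without treated B and -6.78 on thinning. The rise of CRYAB was log2 5.86, or 5.26 without treated D, and that of UNC5B log2 5.38, or 5.99 without untreated C. Such floors and intervals cover counting error only, since the deposited values are read counts. In all 6105 of 15532 genes changed (2870 higher, 3235 lower), 2212 by at least 2-fold. The calls of chaperones and autophagy ended with only the 8 compared libraries fitted (adjusted p = 0.177 and 0.146), and that of chaperones also with every library thinned to the smallest total (0.0628), at a median log2 of 0.907 against 0.847. That of neuronal identity ended with the letters as a block (0.0542) and without untreated D (0.0522) or treated C (0.0747). Those of proliferation, the amino acid response, NRF2, p53 and mitochondrial genome genes held.

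Genes followed across the doses of 2BPA after 1 week, chosen after their values were seen, took different courses. TOP2A was 2.05-fold lower at 5 mM, 9.45-fold at 10 mM and 22.8-fold at 20 mM. The direct comparison of 20 with 5 mM passed the test (log2 -3.47, adjusted p = 9.11e-15). MT-ND2 was 2.34-fold lower at 5 mM and 4.58-fold at 10 mM (1130 ± 259 and 578 CPM), and lower at 20 than at 5 mM (log2 -1.14, adjusted p = 5.45e-10). DDIT3 rose 7.38-fold at 5 mM and 12.4-fold at 10 mM, and was higher at 20 than at 5 mM (log2 0.90, adjusted p = 1.65e-05). TRIB3 stood at 91.6 ± 24.4, 176 ± 16.1 and 177 ± 10 CPM at 5, 10 and 20 mM, and CDKN1A at 488 ± 118, 564 ± 114 and 353 ± 64.1 CPM. Sterol synthesis genes took another course. HMGCS1 rose 2.37-fold at 5 mM (688 ± 114 against 292 ± 60.5 CPM, adjusted p = 2.53e-05) and 2.36-fold at 10 mM. At 20 mM it stood at 321 ± 115 CPM (log2 0.13, adjusted p = 0.659), below the 5 mM level (log2 -1.11, adjusted p = 0.000581). IDI1 rose 2.61-fold at 5 mM and 2.29-fold at 10 mM, and INSIG1, which restrains sterol synthesis, 3.8-fold and 5.4-fold. At 5 mM 17 of 24 sterol genes rose and 2 fell (adjusted p = 0.0765 with an estimated correlation). Between 20 and 5 mM 14 fell, or 16 over the list alone (camera adjusted p = 0.00336). At 20 mM 8 of the 24 rose and 5 fell, the same over the list alone (camera adjusted p = 0.997). Ribosomal protein genes fell between 5 and 20 mM in 25 of 25 cases (camera adjusted p = 0.0199). Their share of counts was 16.2% at 5 mM, 13.1% at 20 mM and 14.5% in untreated libraries.

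**Figure D3:**
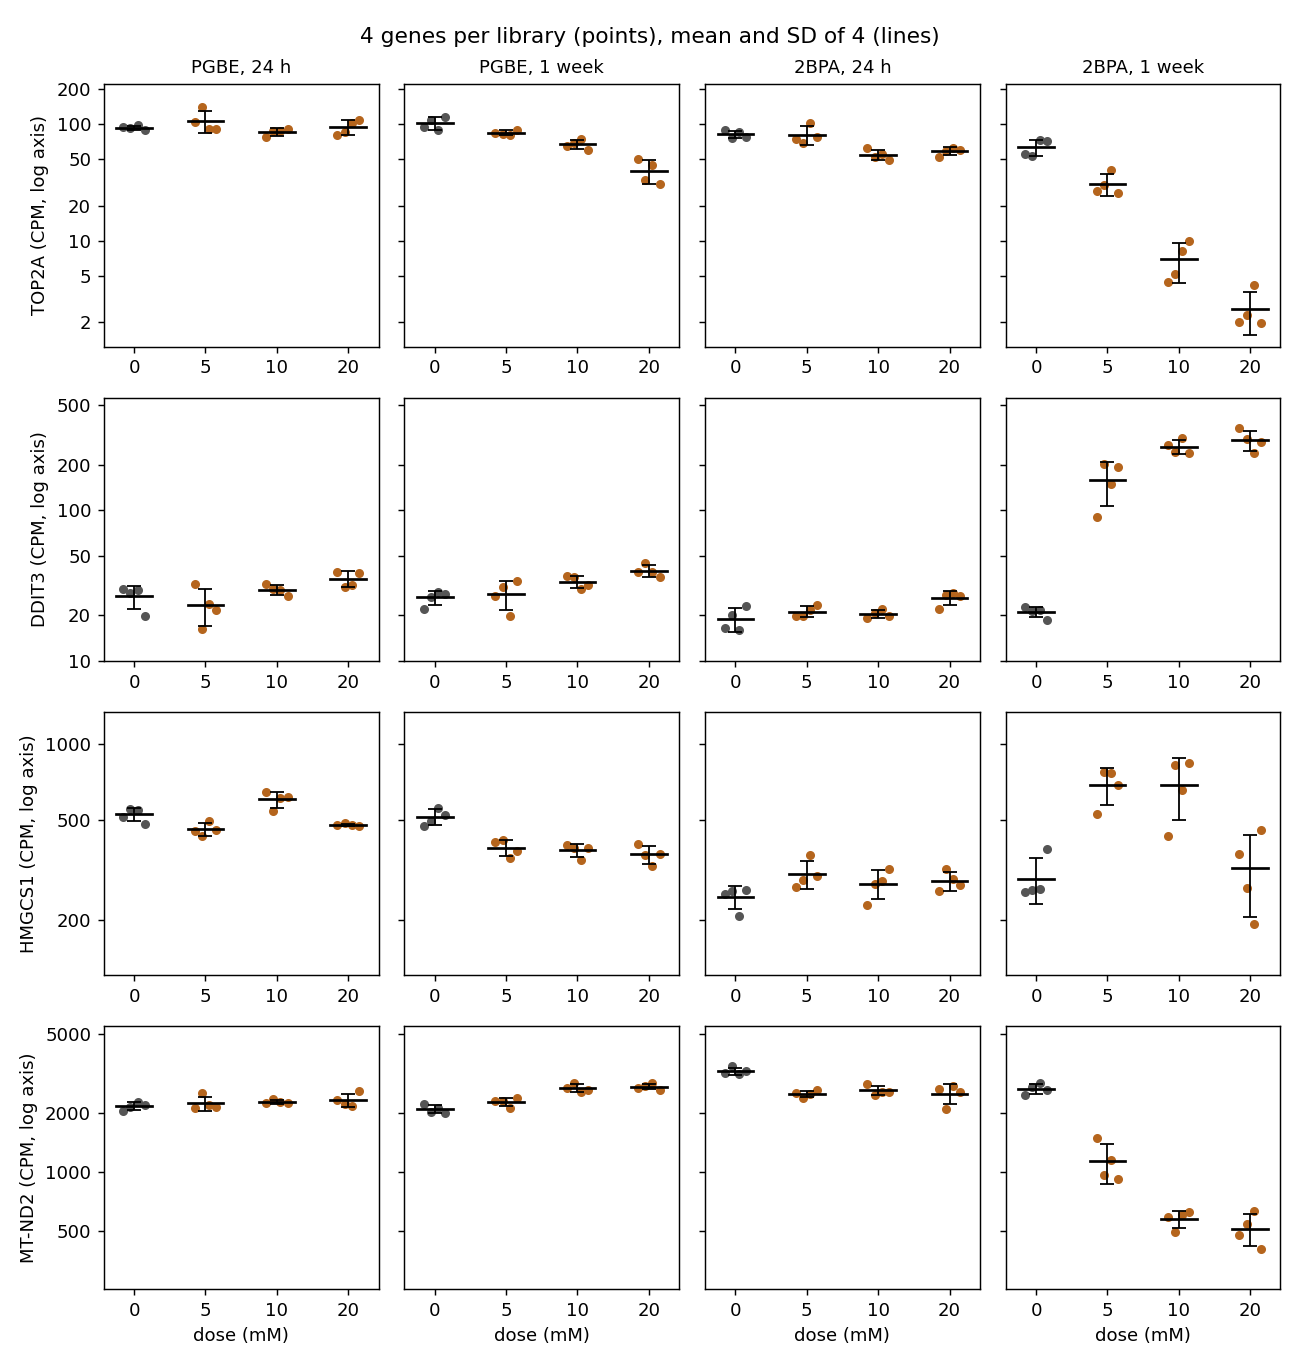
CPM (log axes) of TOP2A, DDIT3, HMGCS1 and MT-ND2 in each library (points), by dose in mM, for both compounds and exposure times, with the mean and SD of 4 libraries (lines). After 1 week of 2BPA, TOP2A runs from 63.5 in untreated libraries to 2.62 at 20 mM and HMGCS1 from 292 to 688 at 5 mM and 321 at 20 mM.

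Against untreated libraries 5450 genes changed at 5 mM 2BPA after 1 week (2806 higher, 2644 lower), 7076 at 10 mM (3306 higher, 3770 lower) and 6105 at 20 mM. CRYAB reached 336 ± 233, 907 ± 325 and 316 ± 240 CPM and GDF15 322 ± 151, 1170 ± 273 and 1020 ± 540 CPM at the 3 doses. Between 20 and 5 mM 1571 genes differed, or 610 with only those libraries fitted, a comparison chosen after seeing the data. Between 20 and 10 mM the number, 590, was not firm. It was 11 with only those 8 libraries fitted and 174 without 10 mM D and 20 mM A together. It was 1311, 207, 345 and 182 without 10 mM A, B, C or D and 248, 116 and 1319 without 20 mM B, C or D. No order of these doses is drawn from it.

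The effects at 20 mM were compared between times as the 1 week minus the 24 h effect. The 1 week groups had 3 exposures and the 24 h groups 1, so repetition and duration cannot be told apart. For PGBE 347 genes differed (194 higher, 153 lower at 1 week). Proliferation genes were lower after 1 week relative to 24 h (13 of them called, camera adjusted p = 3.3e-05, median log2 -0.94). Neural progenitor markers were lower (4 called, 8 over the list alone, camera adjusted p = 0.000722) and neuronal identity genes higher (6 called and 6 over the list alone, camera adjusted p = 0.000722). The amino acid response was not shown to differ (camera adjusted p = 0.618). BUB1 (log2 -2.59, adjusted p = 7.36e-07) and PRR11, a mitotic gene (log2 -1.60 ± 0.221, adjusted p = 1.18e-08), differed downward. COL7A1 (log2 1.79, adjusted p = 0.00156) and PDIA2, a disulfide isomerase (log2 1.68, adjusted p = 0.00468), differed upward. H4C3 (log2 2.15) and MIR124-1HG (log2 2.22) also differed upward, beside the higher untreated levels at 24 h given above. For 2BPA 3701 genes differed (1705 higher, 1996 lower). Proliferation genes (19 called, camera adjusted p = 1.41e-07, median log2 -2.17) and mitochondrial genome transcripts (8 called, camera adjusted p = 0.00504) were lower, and the amino acid response (15 called, camera adjusted p = 5.75e-05) and NRF2 targets (12 called, camera adjusted p = 0.000117) higher. NGFR, the low-affinity neurotrophin receptor, stood at 89.8 ± 28.1 against 4.61 ± 1.02 CPM after 1 week (difference of effects log2 5.43 ± 0.557, adjusted p = 5.26e-10). ICAM1 (log2 5.46, or 4.39 without untreated 24 h D, adjusted p = 3.12e-07) and GDF15 (log2 6.24, adjusted p = 3.28e-08) differed likewise. Genes changed in the same direction at both times numbered 54 higher and 33 lower for PGBE, against 4.68 and 6.39 for independent lists. Opposite changes exceeded independence too, with 17 lower at 24 h and higher after 1 week against 5.67, and 7 the other way against 5.27. For 2BPA 84 were higher and 106 lower at both times, against 23.8 and 36.4, and 19 and 9 went opposite ways, against 32.3 and 26.9. The 2BPA sum of 190 was 665 with only the compared libraries fitted, 445 with DESeq2 and 93 on thinning. It was 76, 76 and 122 without untreated 24 h B, C or D and 115, 109, 82 and 99 without 20 mM 24 h A, B, C or D.

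Untreated spheroids were compared between the collection times as well. BCAN, a proteoglycan of glia and their progenitors, was higher after 1 week in both runs, at 137 ± 18.2 against 76.7 ± 6.85 CPM beside PGBE (log2 0.84, adjusted p = 3.16e-13) and 134 ± 13.8 against 59.8 ± 6.87 CPM beside 2BPA (log2 1.16, adjusted p = 4.15e-07). Beside PGBE the thyroid hormone binding protein gene CRYM (67.6 ± 2.84 against 34.9 ± 3.3 CPM) was higher. Astrocyte markers rose as a list (2 called, 4 over the list alone, camera adjusted p = 0.000732), as did progenitor markers (2 called, 4 over the list alone, camera adjusted p = 0.00365). Beside 2BPA the pericyte receptor PDGFRB (26.5 against 9.51 CPM, adjusted p = 0.00104) and FAM107A (22.8 against 8.44 CPM, adjusted p = 0.00288) were higher and ID3 lower (33 against 66.5 CPM, adjusted p = 0.00136). There, proliferation genes were lower as a list with 6 called over the list alone and none by edgeR over all genes (camera adjusted p = 3.58e-05, median log2 -0.37). In all 58 genes differed beside PGBE, 37 without 24 h A and 35 without 1 week C. It was 42 genes beside 2BPA, and 23, 17 and 22 without 24 h B, C or D and 24, 14 and 24 without 1 week A, B or D. The 2BPA number was 408 with only those 8 libraries fitted, 238 with DESeq2, 84 with the background covariate and 65 without the libraries that stood apart.

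The parent compound and its metabolite, 1 with an alcohol and the other with a carboxylic acid group, were compared at matched doses and times as the difference of their effects, each against its own untreated libraries. The 2 compounds were measured in separate sets of libraries. A response that differed between these sets for another reason cannot be told apart from a difference between compounds. After 24 h at 20 mM the amino acid response was higher with both and was not shown to differ (camera adjusted p = 0.85). The difference, PGBE minus 2BPA, was log2 0.37 for MTHFD2 (95% interval 0.0883 to 0.655, adjusted p = 0.259). It was 0.13 for SESN2 (-0.209 to 0.471, adjusted p = 0.857) and -0.57 for SLC7A11 (-1.24 to 0.102, adjusted p = 0.572), so differences within these intervals are not excluded. TFRC responded less to PGBE at every dose at 24 h, by log2 -1.18 at 5 mM (95% interval -1.54 to -0.817, adjusted p = 3.41e-05), -1.48 at 10 mM (-1.84 to -1.12, adjusted p = 4.5e-09) and -1.11 at 20 mM (-1.46 to -0.758, adjusted p = 1.49e-05). TFRC itself rose with 20 mM PGBE at 24 h, 1.5-fold (39 ± 4.24 against 26.1 ± 3.93 CPM, adjusted p = 0.00774), a call that ended without untreated A (0.0948) or treated D (0.0534). Proliferation genes were lower with 2BPA than with PGBE at 24 h as a list at 5, 10 and 20 mM (camera adjusted p = 0.00132, 0.0161 and 0.000235, with 3, 2 and 9 genes called over the list alone and 0, 0 and 1 by edgeR over all genes). PCLO rose more with PGBE at 20 mM (log2 0.89, 95% interval 0.496 to 1.28, adjusted p = 0.00963). With every library thinned to the smallest total the difference was log2 0.795 and its call ended (adjusted p = 0.0784). CDC20 fell with 2BPA (46.3 ± 2 against 82.1 ± 9.13 CPM, adjusted p = 0.00383) and stood at 60.1 ± 6.8 against 44.7 ± 2.78 CPM with PGBE (difference log2 1.26, adjusted p = 9.53e-05). STMN2 was not shown to differ after adjustment over genes (log2 -0.33, unadjusted 95% interval -0.519 to -0.15, adjusted p = 0.0508).

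**Figure D4:**
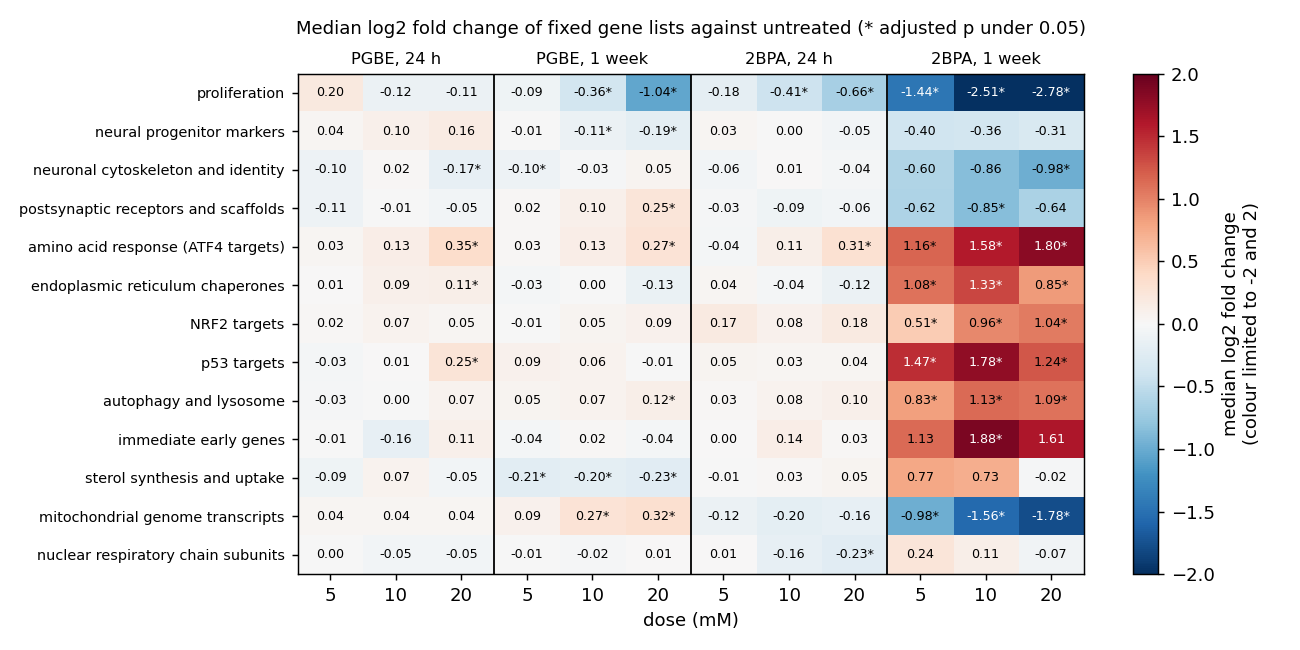
Median log2 fold change against untreated of 13 fixed gene lists (lines of the map) by compound, exposure time and dose in mM (columns), coloured from blue (lower) to red (higher) with the value printed, and a star where camera with an estimated correlation gave an adjusted p under 0.05. At 20 mM after 1 week the median of the proliferation list is -1.04 with PGBE and -2.78 with 2BPA.

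After 1 week the responses measured for the 2 compounds differed widely, with the same limit of separate sets of libraries. At 20 mM the difference was log2 3.13 for TOP2A (95% interval 2.57 to 3.68, adjusted p = 2.17e-17) and 2.71 for MT-ND2 (2.46 to 2.96, adjusted p = 1.18e-28). It was 1.13 for STMN2 (adjusted p = 5.26e-19), -0.82 for MTHFD2 (-1.11 to -0.537, adjusted p = 1.49e-06) and -3.57 for TRIB3 (adjusted p = 1.02e-18). GDF15, up 83.5-fold with 2BPA, stood at 8.97 ± 2.57 against 7.04 ± 1.36 CPM with PGBE (difference log2 -6.07, adjusted p = 1.88e-10). TFRC, 3.38-fold higher with 20 mM 2BPA (113 ± 14.5 against 33.3 ± 1.51 CPM, adjusted p = 1.83e-16), stood at 31.5 ± 4.77 against 33.6 ± 1.92 CPM with PGBE (difference log2 -1.87, 95% interval -2.23 to -1.51, adjusted p = 1.8e-15). Mitochondrial genome transcripts moved in opposite directions at 10 and 20 mM, higher with PGBE and lower with 2BPA, and the effects differed at 5, 10 and 20 mM (camera adjusted p = 0.00229, 1.35e-05 and 3.94e-07). So did proliferation genes (camera adjusted p = 6.88e-06, 9.29e-06 and 3.01e-06) and the amino acid response (6.88e-06, 4.87e-06 and 1.03e-06). At 5 mM HMGCS1, lower with PGBE and higher with 2BPA, differed by log2 -1.67 (adjusted p = 5.61e-08). The sterol list differed at 5 mM (camera adjusted p = 0.00225) and 10 mM (0.0332) and was not shown to differ at 20 mM (0.439). PCLO was not shown to differ at 20 mM (log2 -0.36, 95% interval -0.753 to 0.0325, adjusted p = 0.176).

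The number of genes whose responses differed between the compounds was 1 at both 5 and 10 mM after 24 h, TFRC each time. There were 613 and 829 genes at an unadjusted p under 0.05. At 20 mM it was 131 (76 higher, 55 lower). After 1 week it was 3777, 5389 and 4383 at 5, 10 and 20 mM. By DESeq2 the 24 h numbers at 10 and 20 mM were 14 and 239, with only the compared libraries fitted they were 25 and 421, and on thinning the 20 mM number was 54. At 5 mM the compared libraries alone gave 5. Leaving out 1 library moved the 10 mM number to 4 (2BPA untreated D), 3 (2BPA 10 mM D) or 2 (PGBE untreated A). It moved the 20 mM number to 85 (2BPA untreated B), 86 (2BPA untreated C), 86 (PGBE untreated B) or 80 (PGBE 20 mM A). Genes changed in the same direction by both compounds at 20 mM numbered 15 higher and 22 lower after 24 h, against 1.65 and 2.73 for independent lists. After 1 week they were 105 higher and 236 lower, against 72.1 and 99.2. The 24 h sum of 37 was 116 with only the compared libraries fitted, 71 with DESeq2 and 20 on thinning. It was 21, 21, 22 and 23 without 2BPA untreated B or C or 2BPA 20 mM C or D. At 24 h 6 genes were higher with PGBE and lower with 2BPA, against 2.24 for independent lists, and 2 the reverse, against 2.01. At 1 week the former numbered 114, against 87.1, and the latter 48, against 82.2.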

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

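The tests of depth, background reads, swapped labels and nuclear RNAs were chosen after the results they bear on were seen, and so were the direct comparisons of 2BPA doses. The test of other iron genes was fixed before its outcome was known, but it bears on TFRC, a gene chosen after its values were seen. The counts over other splits of the libraries were set before, except those for the comparisons of 2BPA doses.

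TFRC rose with 2BPA at 24 h at every dose, and the difference from PGBE passed the test each time, and after 1 week as well. Background reads are argued against as the whole cause, since the log2 rise at 5 mM was 1.29 with them as covariate and stayed past the threshold. With every library thinned to the smallest total it was 1.34 and also stayed past the threshold. Thinning keeps each gene's expected share of counts. It therefore shows that the call did not need the full depth, and does not test depth as a cause of the rise. TFRC messenger is stabilised when cells lack iron, so a response to low iron is a candidate explanation. Of 10 other iron genes measured 2, SLC39A14 (log2 0.94, adjusted p = 0.00468) and SLC40A1 (log2 0.77, adjusted p = 0.0433), were called in a 24 h comparison. The iron importer gene SLC11A2 was not called at 24 h (log2 0.54 at 20 mM, adjusted p = 0.0619). The test counted genes called in either direction, so these 2 rises do not by themselves point to low iron. SLC40A1 exports iron, and its rise is no support for a lack of it. SLC39A14 and SLC40A1 were called at 20 mM alone and none of the 10 at 5 or 10 mM, so any support at 24 h is weak. SLC40A1 also lost its call without any 1 of the 8 libraries (0.0761 to 0.156). After 1 week at 20 mM 5 of the 10 were higher and 1 lower. The latter was SLC40A1, lower at 5, 10 and 20 mM (log2 -0.98, -1.71 and -0.93). A response to low iron stays open, as do other responses to the acid.

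More genes were changed at 10 mM than at 20 mM 2BPA after 1 week (7076 against 6105). The ratio of these numbers was 1.16 with the background reads as covariate, which argues against background as the cause. It was 1.17 with every library thinned, which does not test depth, since the 10 mM libraries were already the shallower ones (mean 2426000 against 2975000 counts). Of 36 genes called at 24 h and differing between 20 and 10 mM, 100% lay further in the 24 h direction at 20 mM, but these genes come from the direct comparison, so swapped labels stay open. The direct comparison itself was not firm: 2 of 35 splits of its 8 libraries gave as many genes, the real one included, with 590 in the real split and 1838 in the highest other, so chance is not excluded, other structure among these libraries is present, and no biological explanation was tested.

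Mitochondrial genome transcripts were lower with 2BPA after 1 week, with a median log2 of -1.78 at 20 mM. The median was -1.71 with the background reads as covariate, which argues against background as the cause. It was -1.75 with every library thinned, which does not test depth as a cause, since thinning keeps each gene's expected share of counts. A loss of cytoplasmic RNA from dying cells would leave nuclear RNAs higher. MALAT1 rose (5240 ± 2180 against 1410 ± 268 CPM, log2 1.89, adjusted p = 9.2e-05). Of 9 other nuclear-retained RNAs 3 rose (NEAT1 log2 2.72, PVT1 log2 2.84, LINC-PINT log2 1.53) and 2 fell (RMST log2 -1, TUG1 log2 -0.39). The median log2 of the 9 was -0.019, so a loss of cytoplasmic RNA stays open. An effect of 2BPA on mitochondrial transcription or on the number of mitochondria may be involved and was not tested.

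Differences between times or compounds that passed a test of the difference itself numbered 347 genes for PGBE and 3701 for 2BPA between times, and between compounds 1, 1 and 131 genes at 24 h and 3777, 5389 and 4383 after 1 week at 5, 10 and 20 mM. For PGBE 1 of 100 splits, the real one, gave as many genes between times (highest other 264), and for 2BPA 3 of 100 (highest other 3772). The 2 other splits for 2BPA that reached the real number left the 1 week libraries as labelled. The splits between times mixed treated with untreated libraries at both times at once. They bear on whether there was any effect and cannot decide chance for the difference between times. Of 48 splits drawn for each compound difference, only the real one gave as many genes at 24 h and 20 mM (131, highest other 17). The same held after 1 week at 5, 10 and 20 mM (3777, highest other 633, 5389, highest other 112, and 4383, highest other 854). At 24 h and 10 mM 2 splits gave 1 gene (highest other 1), and the other split left the PGBE libraries as labelled. At 24 h and 5 mM 3 splits gave 1 gene (highest other 1), and chance is not excluded. These splits mixed treated with untreated libraries within both compounds at once, and 0 other splits drawn left the 2BPA libraries as labelled. They therefore bear on whether either compound had an effect and cannot decide chance for the difference between compounds.

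Chance marks about 1 in 20 groups of 4 by the measure used here, and 9 of 96 groups were marked for library measures and 4 of 80 for named genes. Total counts were low in 2BPA untreated 1 week D (2827011, others 5201566 to 5608165) and PGBE untreated 24 h D (2758555, others 4827464 to 5150847). Genes detected were few in PGBE untreated 24 h D (16634, others 18142 to 18317) and PGBE 20 mM 1 week A (16893, others 17197 to 17228). The mitochondrial share was low in 2BPA 20 mM 1 week D (2.859%, others 3.073% to 3.091%). Olfactory receptor CPM was high in 2BPA 10 mM 1 week A (230.6, others 27.08 to 61.57), 2BPA 5 mM 1 week D (122.1, others 12.4 to 17.31) and PGBE 5 mM 1 week A (8.63, others 3.2 to 3.858) and low in PGBE untreated 1 week A (3.356, others 4.757 to 4.971). Among named genes after 1 week of 2BPA or none, GDF15 stood at 12.9 CPM in untreated C (others 11.7 to 11.9), HSPB8 at 0.555 in untreated A (others 0), ICAM1 at 37.1 in 20 mM C (others 55.9 to 59.4) and TK1 at 0.21 in 20 mM B (others 0).

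For the comparisons with untreated libraries, 35 splits of the 8 libraries were counted. As many genes came from 1 split, the real one, in 11 of the 12 dose comparisons. This is the smallest share that 35 splits allow, with no adjustment over the comparisons, so it argues against chance there without excluding it. The margin was small where the numbers were small, as for 5 and 10 mM 2BPA at 24 h and 5 mM PGBE after 1 week. The numbers for PGBE were 64 (highest other 1) and 387 (15) at 10 and 20 mM after 24 h, and 7 (4), 46 (2) and 787 (17) at 5, 10 and 20 mM after 1 week. For 2BPA they were 1 (0), 4 (0) and 304 (1) at 24 h and 5450 (2415), 7076 (1945) and 6105 (1297) after 1 week. The exception was 5 mM PGBE at 24 h, where 2 of 35 splits gave 3 genes (highest other 3), and chance is not excluded. Untreated libraries differed between times in 1 of 35 splits, the real one, beside PGBE (58, highest other 2) and beside 2BPA (42, highest other 1), and 20 with 5 mM 2BPA likewise (1571, highest other 1161).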

How the results depend on the processing

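No call of a gene or list turned direction under any setting run. Of 453 gene results followed, 116 lost their call somewhere, 106 under a setting fixed beforehand and 105 on leaving out 1 library. Of 24 list calls 15 did, 14 under a setting fixed beforehand and 5 on leaving out 1 library. These 24 list calls are those of the 4 main comparisons. Lists called in other comparisons (other doses, times, untreated libraries or compounds) were not refitted under these settings, so how firm they are is not known. Thinning, the background covariate and leaving out 4 libraries that stood apart were chosen after seeing the data, as were both comparisons of 2BPA doses. The letters A to D did not pair the libraries: 2 of 48 correlations of same-letter deviations were over 0.1 (range -0.31 to 0.18). With the replicate block the genes differing between compounds at 24 h and 10 mM numbered 3, not 1, the 1 week 2BPA neuronal list lost its call (adjusted p = 0.0542), and no other count moved by over 1.5 times. Except where construction shows it (fewer libraries or counts), the cause was not tested.

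Fitting only the compared libraries gave, for PGBE, 5 genes at 24 h and 5 mM, 12 and 80 after 1 week at 5 and 10 mM, for 2BPA 2, 293 and 1494 at 24 h, 408 between untreated libraries, 11 and 610 for 20 mM against 10 and 5 mM, for the compound differences at 24 h 5, 25 and 421, and for shared genes 665 (2BPA, both times) and 116 (both compounds, 24 h). DESeq2 gave 115 for PGBE at 24 h and 10 mM, 25 and 113 after 1 week at 5 and 10 mM, 51 and 789 for 2BPA at 24 h and 10 and 20 mM, 238 between its untreated libraries, 1170 for 20 against 10 mM, 14 and 239 for the differences at 24 h and 10 and 20 mM, and 445 and 71 shared genes. Without a filter PGBE at 24 h and 10 mM gave 32 and the difference at 10 mM 3, and with DESeq2-style size factors the latter gave 2. Thinning gave 0 for PGBE at 24 h and 5 mM, 141 for 2BPA at 24 h and 20 mM, 54 for the difference, and 93 and 20 shared genes, which shows what depth limits. Leaving out the 4 libraries gave 40 for PGBE at 24 h and 10 mM, 65 for untreated 2BPA, 3 for the difference at 10 mM and 174 for 20 against 10 mM, and the covariate 84 for untreated 2BPA and 3 for the difference.

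Leaving out each library in turn gave, for PGBE, 0 to 4 genes at 24 h and 5 mM, 20 to 60 at 10 mM and 258 to 348 at 20 mM. After 1 week it gave 3 to 10, 23 to 46 and 582 to 745. For 2BPA it gave 1 to 4 at 24 h and 10 mM and 101 to 249 at 20 mM, and after 1 week 4643 to 5908, 6487 to 7023 and 5429 to 5992. Untreated libraries gave 35 to 53 beside PGBE and 14 to 37 beside 2BPA. The compound differences at 24 h gave 1 to 4 at 10 mM and 80 to 114 at 20 mM, and 20 against 10 mM 2BPA gave 116 to 1319. Shared genes ran from 76 to 182 for 2BPA at both times and from 21 to 37 for both compounds at 24 h.

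Lists lost with only the compared libraries were neuronal (0.102), amino acid (0.0836), chaperone (0.102) and p53 (0.15) genes with PGBE at 24 h, presynaptic (0.125), postsynaptic, astrocyte, progenitor and amino acid (0.0573 each) and autophagy (0.149) genes with PGBE after 1 week, and chaperone (0.177) and autophagy (0.146) genes with 2BPA after 1 week. Thinning ended 2BPA 24 h amino acid (0.0631) and respiratory chain (0.109), 1 week chaperone (0.0628) and PGBE 1 week presynaptic (0.0619) calls. Those of presynaptic and autophagy genes with PGBE after 1 week also ended without a filter (0.0902 and 0.0539) and with the covariate (0.054 and 0.0564). The calls of proliferation (3 of the 4 main comparisons), sterol and mitochondrial genes with PGBE, and amino acid, NRF2, p53 and mitochondrial genes with 2BPA after 1 week held under every setting.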

Other observations

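All values in this part were chosen after the data were seen, apart from the gene lists they come from.

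After 1 week of 20 mM 2BPA several further gene groups held members that moved, though none of these lists passed camera with an estimated correlation. Immediate early genes rose in 10 of 12 cases and NR4A2 fell (adjusted p = 0.102 with an estimated correlation), with FOS at log2 3.02, EGR1 at log2 2.12 and ARC at log2 1.96. Hypoxia and glycolysis genes went both ways, 7 higher and 2 lower of 19 (adjusted p = 0.108): the angiogenic factor VEGFA (log2 2.24) and the mitophagy receptor BNIP3 (log2 1.44) rose, and lactate dehydrogenase LDHA fell by 1.69 on the log2 scale. Interferon response genes rose in 6 of 12 cases (adjusted p = 0.149), led by the class I antigen gene HLA-B (log2 1.83) with its partner B2M (log2 0.82). Fatty acid synthesis genes fell in 8 of 13 cases and ACSL3 rose (adjusted p = 0.191), with the citrate lyase ACLY at log2 -1.07 and the synthase FASN at log2 -0.61. CPT1A, which admits fatty acids to mitochondria for oxidation, rose (log2 2.19), within a list of which 7 rose and 3 fell of 17 (adjusted p = 0.538).

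Markers of cell types that BrainSpheres could hold besides neurons and glia moved apart within their lists at the same dose and time. Of 9 mesenchymal markers the proteoglycan LUM rose (38.1 against 6.05 CPM, log2 2.70) with fibronectin FN1, while the collagen COL1A2, PDGFRB and THY1 fell (adjusted p = 0.538). The cilium regulator FOXJ1 (log2 -1.95) and TPPP3 (log2 -0.86) were lower, 2 of 6 choroid plexus and ependymal markers (adjusted p = 0.626). Transmitter genes fell in 3 of 9 cases and 1 rose (adjusted p = 0.414), among them GAD2, which makes GABA (log2 -1.43), and DDC, of dopamine and serotonin synthesis (log2 -2.08).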
